A study of Actinoplanes siamensis with 11 samples.

How the data were processed

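RNA sequencing was carried out on 11 libraries of Actinoplanes siamensis TBRC 4237, an actinomycete bacterium, grown in LS2 liquid medium at 30 °C. Per the labels, the organism was first grown on agar, pieces of which were used to inoculate baffled flasks, and cells were collected at 66, 72 and 90 h. There were 4 libraries at 66 h, 4 at 72 h and 3 at 90 h. No treatment was applied, so the time of cultivation is the sole group. Per the labels' protocols, total RNA was treated with DNase and sequenced as paired-end reads on an Illumina NovaSeq instrument. Whether and how ribosomal RNA was removed, whether libraries kept strand, and the aligner, the counting program, the genome build and the annotation are not given in the sources used here.

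The authors deposited a single table of whole-number read counts per gene for 7960 genes, with 1 column per library and no normalization. Columns were assigned to samples by the library name in the labels, and 0 columns were left without a sample. At 90 h the library names carry the numbers 2, 3 and 4 while the titles number the replicates 1, 2 and 3. Replicates are named here by the title. Per the file's row names, 5 further rows name no gene. They hold reads in no annotated gene, reads that overlap more than 1 gene, reads of low alignment quality, reads not aligned and reads aligned to several places. Pooled over the libraries these took 2.40%, 6.60%, 0.106%, 1.72% and 0.986% of the table's total, and they were left out of library sizes and tests. If those names are taken at their word, reads that overlap more than 1 gene are absent from the counts of these genes, which lowers the values of overlapping or closely spaced genes.

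Gene identifiers have the form fig|201174.113.peg.N and are shortened here to peg.N. The file pairs them with no symbol, product, position or length, and no genome or annotation was used here. Values in CPM, read counts scaled to a common library total, are therefore not corrected for gene length, and a long gene reaches a higher CPM than a short gene transcribed at the same rate. The 34 gene lists that had been fixed before the data were examined (ribosomal proteins, respiration, secondary metabolism, sporulation and the like) need symbols or product text. With 0 lists matched, the planned tests of gene lists were not run. The definition of steady genes below was planned without ribosomal and transfer RNA genes. All gene rows carry identifiers of the single form peg.N and none is marked as a ribosomal or transfer RNA gene, so no row was removed. The planned ranking by counts per kilobase was not run for want of gene lengths.

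Total gene counts ranged from 11649479 to 15541702 per library, with a mean of 12964520 ± 1140165 (SD, n = 11). Of the 7960 genes, 21 had no count in any library. Between 93 and 123 genes had a count of 0 in a given library. No 2 libraries of a time agreed within sampling noise. The chi-square statistic per degree of freedom, about 1 for 2 draws from 1 library, was lowest at 9.22, for replicates 1 and 2 at 90 h.

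Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were kept with filterByExpr by time (default settings, a minimum count of 10 and a minimum total of 15), which left 7581. Library sizes were scaled by TMM. All 11 libraries entered 1 quasi-likelihood fit (glmQLFit, glmQLFTest) with time as the sole factor, so that the 3 times share an estimate of the spread. The comparisons were 72 h against 66 h, 90 h against 66 h, 90 h against 72 h, and a joint test of any difference over the 3 times. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes were taken as the absolute log2 fold change divided by the square root of F.

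A steady, highly expressed gene was defined before the data were examined. It had to lie in the top 5% of tested genes by mean CPM at each of the 3 times, with the 95% interval of all 3 pairwise log2 fold changes inside -1 to 1. The rule for named genes was fixed at the same point. Per comparison it took the 2 genes with the largest rise and the 2 with the largest fall among called genes with a mean of at least 10 CPM and no overlap between the libraries of the 2 times. It added the 20 most abundant genes of the steady set. These numbers are those the rule gave for identifiers without a product name.

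The fit was tested on simulated counts drawn from the real means, library sizes and dispersions of the 7581 genes, with 200 genes changed. For 72 h against 66 h, 58% of genes changed by 1 and 93% of genes changed by 2 on the log2 scale were recovered. For 90 h against 66 h these shares were 46% and 90%, and for 90 h against 72 h 34% and 90%. False calls made up 3.21%, 7.48% and 2.36% of the calls in these 3 simulations. Counts were drawn independently for each gene and library. Deviations shared between genes or between same-numbered libraries were thus left out, and the shares in the real libraries may differ. Of the unchanged genes in the top 5% at each time, 283 of 320, 291 of 328 and 293 of 324 met the definition of steady expression, and 0 genes changed by 2 on the log2 scale did.

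Titles give replicate numbers at every time, without stating what a number marks. Deviations from the time means of log2 CPM (prior count 2) were correlated between same-numbered libraries. Between 66 h and 72 h the correlations were 0.47, 0.50, 0.19 and 0.45 for numbers 1 to 4. The 72 h library of number 3 correlated more closely with a 66 h library of another number. The numbers were still taken to pair these libraries, though the labels state no pairing. The main fits, with time as the sole factor, do not use this pairing. Fits with the number as a block are given as alternatives. Between 90 h and the other times, at least 1 correlation fell below 0.1 under either numbering, so no pairing was taken there. The labels do not say whether libraries of a time came from separate flasks, so p-values measure the spread between these samples.

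Alternatives covered DESeq2 1.42.0 and limma-voom (limma 3.58.1) in place of edgeR, 3 other scalings, other low-count filters, fits with the replicate number as a block, fits on the 2 times compared, and leaving out each library. For the steady set, the top 10% and a margin of 1.5-fold were tried. Runs of consecutively numbered genes were counted after the data had been seen, as runs of at least 3 genes called in the same direction, and compared with 10000 random shuffles of the calls over the 7581 tested genes.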

Results

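RNA was sequenced from Actinoplanes siamensis TBRC 4237 at 66 h (n = 4), 72 h (n = 4) and 90 h (n = 3) of growth in LS2 medium, at 11649479 to 15541702 gene counts per library. The series title concerns natural constitutive promoters. The data were therefore read for genes that stayed high and steady over the 3 times, and for genes that changed. Expression was spread over many genes. The 10 most abundant genes of each library held 4.86 ± 0.220% of its gene counts (SD, n = 11). Libraries of the same time correlated across genes with r from 0.97 to 0.99 at 66 h, 0.95 to 0.98 at 72 h and 0.95 to 0.99 at 90 h.

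The first principal component of log2 CPM took 50.1% of the variance and the second 16.9%. On the first component the 66 h libraries lay between -32.9 and -14.0 and the 90 h libraries between 22.6 and 66.2. The 72 h libraries were spread from -32.3 to 18.9 and overlapped the 66 h range as a group. Within each number, by which 66 h and 72 h libraries were taken as pairs, the 72 h library lay higher on this component than its 66 h partner, from -14.0 to 1.14, -32.9 to -32.3, -26.9 to -10.6 and -15.3 to 18.9 for numbers 1 to 4. Along the change from the other 66 h libraries (0) to the 90 h mean (1) these 4 shifts, computed after the positions were seen, were 0.22, 0.012, 0.21 and 0.51, all toward 90 h (exact two-sided sign test p = 0.125, the smallest 4 pairs can give). Replicate 2 at 72 h lay at -32.3, beside replicate 2 at 66 h at -32.9. Replicate 4 at 72 h lay at 18.9, close to replicates 1 and 2 at 90 h at 23.2 and 22.6. Replicate 3 at 90 h stood apart from every other library, at 66.2 on the first and -31.2 on the second component.

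**Figure D1:**
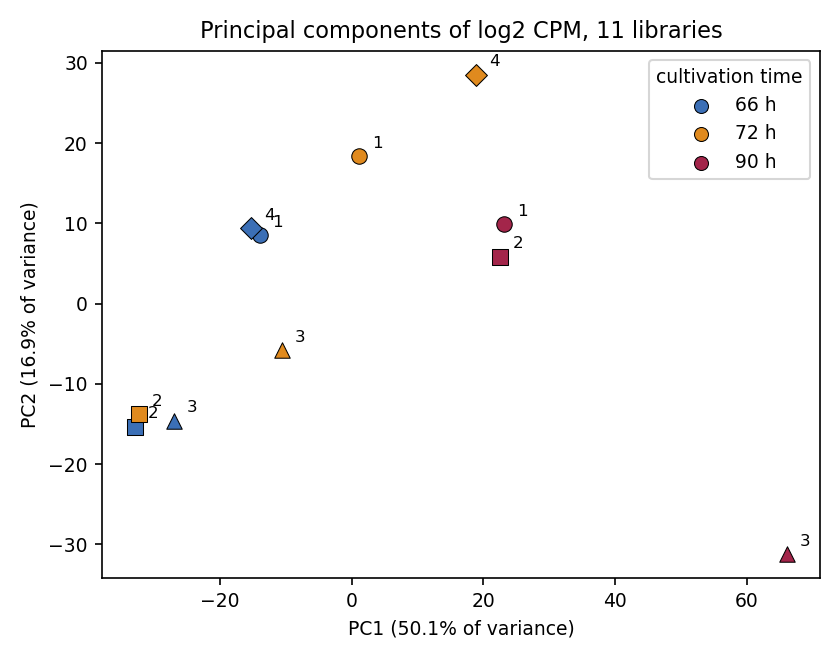
First and second principal components of log2 CPM over 7581 genes; each point is a library, coloured by cultivation time and marked with its replicate number. The 72 h libraries spread widely, with replicate 2 among the 66 h libraries and replicate 4 at 28.5 on the second component, above every other library, and replicate 3 at 90 h lies apart at 66.2 and -31.2.

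The question behind the title is which genes are strongly expressed throughout. These samples answer it only for the 3 times, in a single medium at a single temperature. Earlier times and other conditions were not tested. Genes were ranked by CPM without correction for length, so a high rank is not a measure of transcription rate. Of the 7581 tested genes, 321 lay in the top 5% by mean CPM at all 3 times, and 240 of these also had all 3 pairwise 95% intervals within 2-fold. These 240 genes together held 31.9% of all gene counts. Their mean over all libraries ranged from 573 to 7063 CPM. The median of their largest pairwise log2 difference was 0.23, and their median coefficient of variation over the 11 libraries was 14.6%, compared with 17.3% over the 321. Narrow intervals were part of the choice of the 240, so a lower variation follows in part from it. Of the other 81 highly expressed genes, 32 were called in at least 1 test, and 49 were not called but had intervals too wide to place them within 2-fold.

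By mean CPM over all 11 libraries the most abundant steady gene was peg.2557, at 6729 ± 1890 CPM at 66 h (SD, n = 4), 6711 ± 2238 at 72 h (SD, n = 4) and 7978 ± 64.8 at 90 h (SD, n = 3). It was also among the more variable between libraries of a time, with single libraries from 3609 to 8940 CPM. The gene peg.7504 followed with 7015 ± 691, 7020 ± 789 and 5730 ± 498 CPM at the 3 times (SD, n = 4, 4 and 3), and had the higher mean at 66 h and 72 h. The gene peg.5648 had 5306 ± 381, 5095 ± 913 and 3997 ± 230 CPM. Its largest pairwise log2 difference, 0.41, was larger than that of peg.7504 at 0.29. The consecutively numbered genes peg.570 and peg.571 had means over all libraries of 4474 and 4103 CPM. Of the 20 most abundant steady genes, peg.1807 varied least, at 3516 ± 159, 3411 ± 251 and 3356 ± 318 CPM (SD, n = 4, 4 and 3), a coefficient of variation of 6.60%. For peg.1807 the widest of the 3 intervals reached 0.32 on the log2 scale. The next steadiest, peg.6742, had 3672 ± 315, 3667 ± 383 and 3793 ± 467 CPM (SD, n = 4, 4 and 3) and a coefficient of variation of 9.39%. The gene peg.2672 varied most of the 20, with a coefficient of variation of 28.4% and an interval bound of 0.96, just inside the margin.

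In descending order of mean CPM over all libraries, the other genes of these 20 were peg.676 (3934 CPM), peg.7743 (3717 CPM), peg.7650 (3673 CPM), peg.649 (3597 CPM), peg.577 (3588 CPM), peg.4218 (3218 CPM), peg.1797 (3149 CPM), peg.402 (2881 CPM), peg.856 (2762 CPM), peg.1873 (2745 CPM), peg.7571 (2698 CPM) and peg.5123 (2576 CPM). By the same mean the most abundant 11 genes of the whole table all belonged to the steady set. At 90 h 2 of the 5 most abundant genes, peg.2289 and peg.2294, singled out after their values were seen, were not steady, at 5278 ± 1013 and 5216 ± 153 CPM (SD, n = 3). Steady here means within 2-fold between times, not without change, since 14 of the 240 genes were called at 90 h against 66 h by edgeR's quasi-likelihood test. Single libraries could differ by more, as peg.2557 did with 3609 to 8940 CPM.

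**Figure D2:**
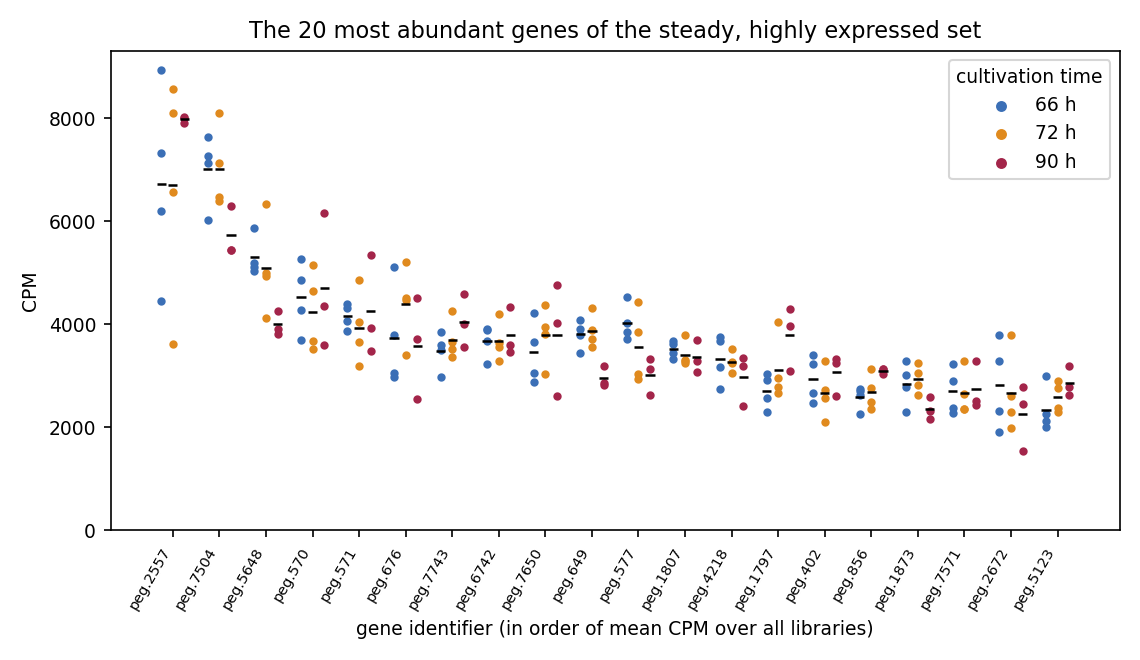
CPM of the 20 most abundant genes of the steady, highly expressed set; each point is a library, coloured by cultivation time, and bars mark the mean of each time. The gene peg.2557, first by mean over all libraries, spans 3609 to 8940 CPM between libraries, while peg.1807 stays between 3074 and 3785 CPM.

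No gene was called between 66 h and 72 h. Of 7581 genes, 0 passed an adjusted p of 0.05 by edgeR's quasi-likelihood test, 331 had an unadjusted p under 0.05 where 379 would be expected by chance, and DESeq2 and limma-voom also called 0. The median absolute log2 difference was 0.15 and the median standard error 0.20. The same test recovered 58% of simulated genes changed by 1 on the log2 scale at this size, so differences that small were not reliably detectable. A fit with the replicate number as a block, on the 8 libraries of these times alone, called 0 genes too, with 978 of 7457 at an unadjusted p under 0.05 where 373 would be expected by chance. Swapping the times within pairs, tried after this count was seen, gave 46 to 686 in the other 7 arrangements, so the real count was the highest of 8, which with 4 pairs is no test at 0.05.

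Between 66 h and 90 h, 1414 genes were called, 18.7% of those tested. Of these, 889 were higher and 525 lower at 90 h, and the fitted rises were larger. At least 2-fold changes comprised 535 rises and 172 falls, and at least 4-fold changes 163 rises and 30 falls. Replicate 3 at 90 h alone lay at least 4-fold above the mean of the other 90 h libraries in 167 genes and below it in 23. The 2-fold and 4-fold counts were not repeated without that library, so how far the larger rises rest on it is open. Of the called genes, 852 rises and 521 falls showed no overlap between the libraries of the 2 times. Over all tested genes 35.4% showed no overlap, where chance gives 5.71%. Without replicate 3 at 90 h, which stood apart in the principal components, 591 genes were called, 377 higher and 214 lower, and 541 of the 591 were among the 1414. Without replicate 2 or replicate 4 at 66 h the calls were 633 and 808.

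The largest rises by the naming rule were in the consecutively numbered genes peg.1055 and peg.1056. From 66 h to 90 h, peg.1055 went from 0.836 ± 0.245 (SD, n = 4) to 152 ± 217 CPM (SD, n = 3), a log2 fold change of 7.49 with a standard error of 1.17 (edgeR adjusted p = 0.00546). The size rested on replicate 3 at 90 h, which had 403 CPM where replicates 1 and 2 had 28.0 and 25.3. Without that library the log2 fold change of peg.1055 was 4.98 (edgeR adjusted p = 0.00943, with 0.000455 to 0.0284 over the alternatives that gave one, DESeq2 not among them). The neighbour in number, peg.1056, went from 1.83 ± 0.493 to 235 ± 348 CPM (SD, n = 4 and 3), a log2 fold change of 6.99 with a standard error of 1.11 (edgeR adjusted p = 0.00558), and 4.19 without replicate 3 at 90 h. They belonged to a run of 7 consecutively numbered genes that all rose, by 0.96 to 7.49 on the log2 scale.

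The largest falls were in peg.2998 and peg.2999, again adjacent in number. At 66 h peg.2998 was at 1211 ± 110 CPM (SD, n = 4) and at 90 h at 80.6 ± 29.1 CPM (SD, n = 3), a log2 fold change of -3.91 with a standard error of 0.58 (edgeR adjusted p = 0.00510). Its 72 h libraries were split. Replicates 1, 2 and 3 had 1062, 1342 and 1123 CPM, within or near the range of the 66 h libraries, and replicate 4 had 181 CPM. The gene peg.2999 fell from 856 ± 103 to 65.6 ± 24.2 CPM (SD, n = 4 and 3), a log2 fold change of -3.71 with a standard error of 0.50 (edgeR adjusted p = 0.00452). Both lay in a run of 6 genes that all fell, with log2 fold changes from -3.91 to -0.88.

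Changed genes occurred together in the numbering. At 90 h against 66 h, 507 of the 1414 called genes (35.9%) lay in 124 runs of at least 3 consecutive numbers with the same direction, 88 runs of risen and 36 of fallen genes. Shuffling the calls over the tested genes gave 38.0 such genes on average and at most 83 in 10000 shuffles (one-sided permutation p = 1e-04, the smallest these shuffles can give). The longest run, singled out after its values were seen, reached from peg.2286 to peg.2299. Its 14 genes all rose, by 0.71 to 1.5 on the log2 scale, and had means over all libraries from 393 to 3584 CPM. They took 1.77% of gene counts at 66 h and 3.35% at 90 h. It held 2 of the 5 most abundant genes at 90 h and 0 genes of the steady set. Fewer genes lay in runs when fewer were called, 128 without replicate 3 at 90 h and 326, 141, 282 and 222 without replicates 1 to 4 at 66 h.

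**Figure D3:**
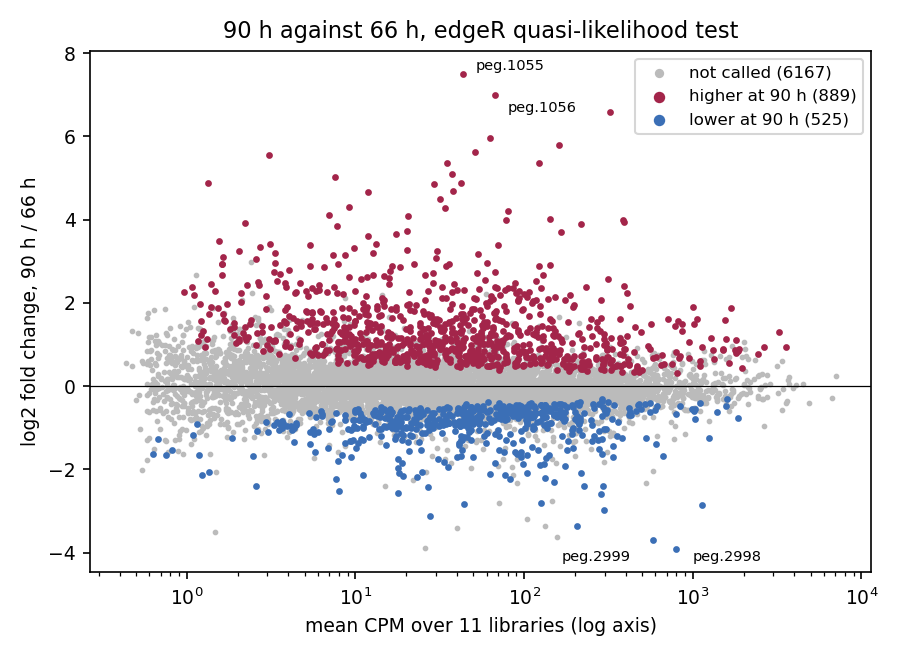
Log2 fold change of 90 h against 66 h (vertical axis) against mean CPM over 11 libraries (log axis), 1 point per tested gene. Coloured points are the 889 genes called higher and the 525 called lower by edgeR's quasi-likelihood test.

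Changes were found at every level of expression. At 90 h against 66 h, 43 of the 379 genes in the top 5% by mean CPM rose and 19 fell. In the next 20% (1516 genes), 169 rose and 136 fell. In the middle 50% (3790 genes) 493 rose and 314 fell, and in the lowest 25% (1896 genes) 184 rose and 56 fell. In replicate 3 at 90 h the lowest 25% lay 0.25 above the other 90 h libraries in median log2, against 0.014 over all genes. How far the rises in this class rest on that library was not tested. The 1414 called genes mostly had the same sign of difference at 72 h against 66 h (95.5%), although 0 of them were called there. The 66 h libraries are shared by both differences, and simulated unchanged groups gave 81.0 to 83.7%. These simulations leave out the pairing by number that was taken for the 66 h and 72 h libraries. With the 1414 genes of lowest p chosen from the 66 h libraries of 2 numbers, and the 72 h difference taken within the other 2 numbers, no 66 h or 72 h library served both. The shares were then 84.2 to 93.5% over the 3 splits that took the 72 h difference with number 4 included and 69.3 to 83.0% over the 3 that did not, and the fits that chose the genes called 0 to 966. Without change these shares would centre on 50%, not on the simulated range above. Their spread is wide, since with the times swapped in 1 of the 2 numbers they were 12.6 to 87.4% with number 4 and 25.2 to 74.8% without it. The median gene showed 28.7 to 40.6% of its 66 h to 90 h difference at 72 h with number 4 and 9.86 to 19.7% without it.

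Between 72 h and 90 h, 154 genes were called, 86 higher and 68 lower at 90 h. All 154 showed no overlap between the libraries of the 2 times. Over all tested genes 18.9% did so, where chance gives 5.71%. The named rises were again peg.1055, with a log2 fold change of 5.12 and a standard error of 1.01 (edgeR adjusted p = 0.0408), and peg.1056, with 4.97 and a standard error of 0.99 (edgeR adjusted p = 0.0408). Without replicate 3 at 90 h these were 2.60 (edgeR adjusted p = 0.109) and 2.17 (edgeR adjusted p = 0.0992), and the adjusted p of the 4 genes named for this comparison reached up to 0.169 over the alternatives that gave one. Leaving out any library at 66 h, or replicate 1, 2 or 3 at 72 h, also took both genes past the threshold (edgeR adjusted p from 0.0585 to 0.110), while the log2 fold changes stayed at 4.74 to 5.32 for peg.1055 and 4.65 to 5.23 for peg.1056. The named falls, peg.3664 and peg.3662, lay in a run of 3 fallen genes. The gene peg.3664 had 14.1 ± 2.75 CPM at 66 h (SD, n = 4), 84.6 ± 101 at 72 h (SD, n = 4) and 3.94 ± 1.41 at 90 h (SD, n = 3). The log2 fold change of peg.3664 from 72 h to 90 h was -4.42 with a standard error of 0.91 (edgeR adjusted p = 0.0408). Replicates 1 and 4 at 72 h had 74.4 and 230 CPM of peg.3664, and replicates 2 and 3 had 15.4 and 18.2, close to the 66 h level. The gene peg.3662 went the same way, with 36.4 ± 4.55, 189 ± 225 and 9.54 ± 1.60 CPM at the 3 times (SD, n = 4, 4 and 3) and a log2 fold change of -4.31 with a standard error of 0.90 (edgeR adjusted p = 0.0417). Without replicate 4 at 72 h the log2 fold changes were -3.19 for peg.3664 and -3.10 for peg.3662, still called. Leaving out any other single library ended both calls (edgeR adjusted p from 0.0585 to 0.137), with log2 fold changes of -4.77 to -4.21 for peg.3664 and -4.67 to -4.24 for peg.3662.

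**Figure D4:**
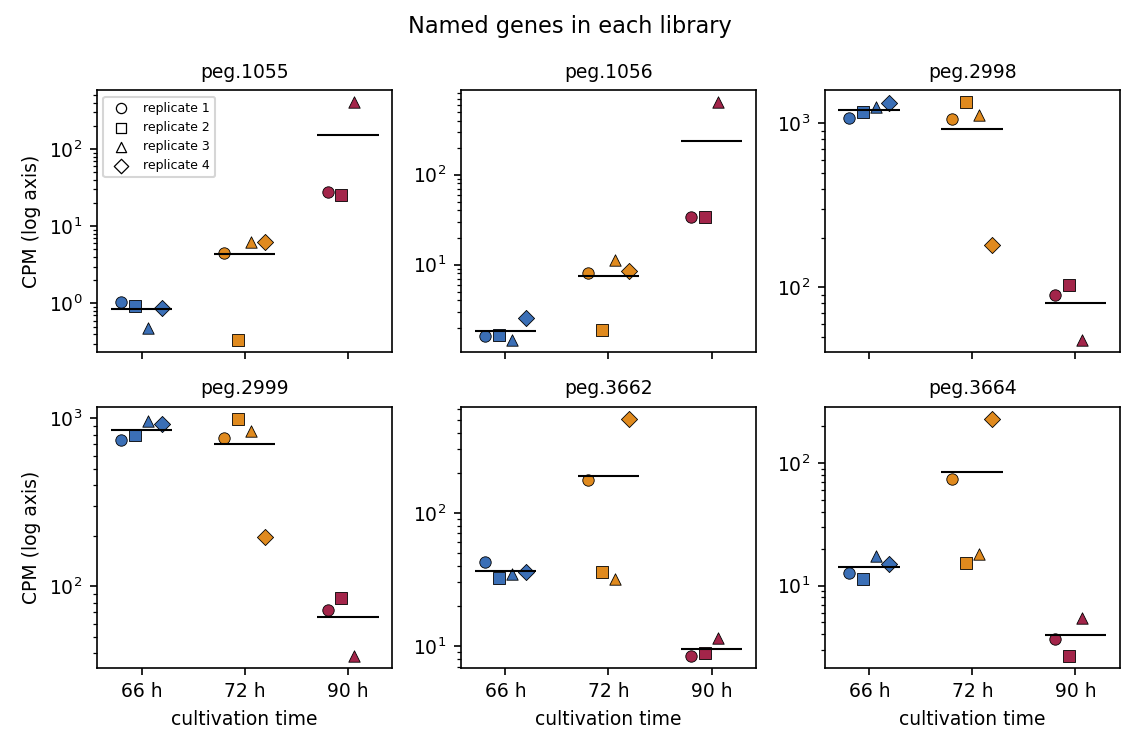
CPM (log axes) of the genes named by rule in each library, by cultivation time; point shapes are replicate numbers and bars mark the mean of each time. For peg.2998, replicate 4 at 72 h lies at 181 CPM, and for peg.3664 replicates 1 and 4 at 72 h lie at 74.4 and 230 CPM.

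The count of 154 depended on single libraries of all 3 times. It was 43, 4, 22 and 14 without replicates 1 to 4 at 66 h, 18, 3, 0 and 562 without replicates 1 to 4 at 72 h, and 217, 251 and 7 without replicates 1 to 3 at 90 h, and a fit of the 72 h and 90 h libraries alone called 0. By other tools, DESeq2 called 713 and limma-voom 67. The joint test over the 3 times called 661 genes, 8.72% of those tested, and 106 without replicate 3 at 90 h. It called 391, 311, 364 and 276 without replicates 1 to 4 at 66 h, 423, 353 and 1022 without replicates 1, 3 and 4 at 72 h, and by other tools DESeq2 called 1342 and limma-voom 436.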

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

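The tests of cultures at different points, of the same-numbered libraries, of genomic DNA, of a library further along, of runs against shuffled calls, of the splits for 72 h against 66 h and of the joint splits by pairs were chosen after the result was seen.

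Replicate 3 at 90 h stood apart and differed by at least 4-fold from the mean of the other 90 h libraries in 190 genes, 167 of them higher, where each of the other 10 libraries differed from the rest of its time in 12 to 83 genes. On the axis from the mean 66 h profile (0) to the mean 90 h profile (1), with itself left out, it lay at 1.25, and its difference from 1 other library at 90 h followed the 66 h to 90 h change of the remaining one with r = 0.23 and 0.24 across genes (95% block bootstrap intervals 0.15 to 0.30 and 0.16 to 0.31). A library further along the same changes stays open at these values, since both r lie under the 0.4 set for it and neither interval lies wholly under the 0.2 set against it. Genomic DNA stays open as well: the lowest-expressed 25% of genes lay 0.25 higher in the median on the log2 scale, against 0.014 over all genes, and 33.0% of them were lower than in the other 90 h libraries, while the share of reads in no gene (2.47%) lay inside the 2.27 to 2.52% of the other 10 libraries. A ratio of gains, tried after that mixed outcome (median 53.7 CPM for the 167 higher genes against 0.508 CPM for the lowest 25%), used genes picked for being higher and so excludes nothing.

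Replicate 4 at 72 h lay toward the 90 h libraries, and libraries of the same number at 66 h and 72 h deviated together. Its deviation from the other 72 h libraries followed the 66 h to 90 h change with r = 0.54 across genes (95% block bootstrap interval 0.50 to 0.59), while replicate 2 at 72 h had r = -0.58. The r of 0.54 restates its position toward 90 h, and a wrong time label would give it as well. The matched numbering gave a mean correlation of 0.40, the highest of the 24 pairings (next highest 0.38, exact one-sided permutation p = 0.0417, the smallest possible), which argues narrowly against chance. Replicate 4 at 66 h leaned weakly toward 90 h too (r = 0.12 with the 72 h to 90 h change, with 0.18 for replicate 1 at 66 h), replicate 3 at 90 h, number 4 by library name, deviated weakly with it (r = 0.17, its best partner at 72 h, but 0.0031 with number 4 at 66 h), and these values fit cultures sampled at different points of one time course, as a hypothesis. A wrong time label also stays open. The library lies at 0.63 on the axis from the mean 66 h profile (0) to the mean 90 h profile (1). Replicates 1 and 2 at 90 h lie at 0.65 and 0.66, but with each left out of its own 90 h mean. In those means the outlying replicate 3 weighs more, so the values are not on the scale of the 0.63. On the first principal component the library lies at 18.9, beside replicates 1 and 2 at 90 h at 23.2 and 22.6. On the second it lies at 28.5 against 9.92 and 5.86. The library has 19 genes at least 4-fold above every 66 h and 90 h library. This is within the 0, 0 and 100 of the 3 libraries at 90 h, set against the 66 h and the other 90 h libraries. The 100 came from replicate 3.

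Called genes lay in runs of consecutive numbers, with 507 genes in runs against at most 83 in shuffled calls. Reads shared between adjacent genes would couple next neighbours alone. Deviations within a time correlated with a mean r of 0.37 for adjacent numbers, 0.21 at 2 apart, 0.11 at 5 apart and 0.077 at 10 apart, against 0.0046 for random pairs. At 50 and 200 apart the mean r was still 0.029 and 0.031, so a small part of the excess was not local. The excess of 0.104 at 5 apart argues against shared reads as the whole cause. If the row names are taken at their word, reads that overlap several genes were also left out of these counts. Such reads could then not be counted for both neighbours. Numbers that follow the genome, with neighbouring genes transcribed or regulated together, are a candidate explanation that needs positions to test.

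Splits of the libraries bear on the counts of called genes. For 90 h against 66 h, 1 of 35 splits, the real one, gave 1414 genes, and the highest of the others gave 0. This share of 2.86%, the smallest that 35 splits can give, argues against chance without excluding it. For 90 h against 72 h, 2 of 35 splits gave at least the real 154, and chance cannot be excluded. The larger count, 345, came from moving replicate 4 at 72 h to the 90 h side. For 72 h against 66 h all 35 splits gave at least the real count of 0, and the highest gave 286, from numbers 1 and 4 against numbers 2 and 3 over both times. That split points to a structure of the samples by replicate number. The 8 splits that part every same-numbered pair all gave 0. For the joint test, 2 of 100 splits (99 of them drawn at random) gave at least the real 661, a share under 0.05. The other of these gave 1214. It grouped replicate 4 at 72 h with replicates 2 and 3 at 90 h, and replicates 2 and 3 at 66 h with replicates 2 and 3 at 72 h. That grouping partly follows the order on the first principal component. Whether it reflects the change with time or another structure of the samples was not tested. Free draws also ignore the pairing of 66 h and 72 h libraries by number, which the labels do not state. Of the drawn splits, 34 parted all 4 pairs, as the real times do, and the highest of these gave 30. The pairing was taken from these data and this set of splits was chosen after the result was seen, so it does not exclude chance.

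Of 68 groups of 4 values tested for a library far from the others, 3 had one, where chance gives about 1 in 20. The share of low-quality alignments was 0.107% in replicate 1 at 66 h against 0.116 to 0.117% in the others of that time. The share of reads aligned to several places was 1.16% in replicate 3 at 72 h against 0.948 to 0.968%. The steady gene peg.1807 had 3785 CPM in replicate 2 at 72 h against 3250 to 3316 CPM.

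Of the reads assigned to no gene, all kinds above the limit a count of 0 allows, reads overlapping several genes took 6.60% of the total (6.39 to 6.80% per library), reads in no gene 2.40%, unaligned reads 1.72%, reads aligned to several places 0.986% and low-quality alignments 0.106%.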

How the results depend on the processing

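The fits with a block on the 66 h and 72 h libraries alone, with a block and without replicate 3 at 90 h, and with robust quasi-likelihood were added after the data had been seen. The count of 0 genes at 72 h against 66 h held under all 24 alternatives run, blocked fits included, with 122 to 1125 genes at an unadjusted p under 0.05. At 90 h against 66 h, scaling and filter changes gave 1288 to 1423 genes. Leaving out 1 library gave 591 (without replicate 3 at 90 h) to 1722 (without replicate 4 at 72 h). At 90 h against 72 h, leaving out 1 library gave 0 to 562 genes, the fit of the 2 times alone 0, DESeq2 713 and limma-voom 67. For the joint test, leaving out 1 library gave 106 to 1022 genes, DESeq2 1342 and limma-voom 436. With the replicate number as a block, the counts for 90 h against 66 h, 90 h against 72 h and the joint test were 2241, 576 and 1278 by title numbers, 1828, 643 and 1022 by library name numbers, and 2219, 999 and 1466 by library name numbers without replicate 3 at 90 h. At 90 h the numbers share only a number with the other times, and 1 or 2 of the 3 libraries correlated best with their own number, so this is no measure of effect size. The steady set held 223 to 248 genes when a library was left out and 207 to 247 under other scalings, filters and blocks. The top 10% gave 495 genes and a 1.5-fold margin 126, as those limits are wider and narrower by construction. The causes of the other shifts were not tested. The folds of the named genes kept their direction in every alternative that gave an adjusted p. These genes were picked for no overlap between libraries, so leaving out a library could hardly have reversed them. At 90 h against 66 h all 4 stayed called where an adjusted p was given, and at 90 h against 72 h peg.1055 and peg.1056 lost their call in 10 of 22 alternatives and peg.3662 and peg.3664 in 12 of 23. DESeq2 gave no adjusted p for peg.1055 and peg.1056. All 20 steady genes named kept their mean CPM within 1 SD between single libraries, a limit that leaving out 1 of 11 libraries could not pass. In simulated counts for 90 h against 66 h (7581 genes), 5 of 28 genes changed by 1 on the log2 scale were recovered in the lowest-expressed 25%, 21 of 40 in the middle 50%, 16 of 26 in the next 20% and 4 of 6 in the top 5%. The planned gene list tests and the ranking by counts per kilobase were not run, for want of names and lengths. No row was removed as a ribosomal or transfer RNA gene, since none was marked as one.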

Other observations

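The test below was set down before its result was seen, and the test by shifts along the numbering was chosen after. A small group of genes was high in single libraries at 72 h, mostly in replicate 4, and not in the 72 h group as a whole. In replicate 4 at 72 h, 19 genes with at least 10 CPM were at least 4-fold above every 66 h and every 90 h library, among them peg.3662 and peg.3664. Of the 19, 13 lay in 3 runs of consecutive numbers, the longest of 6 genes. In replicate 1 at 72 h, 7 genes met the same limit, and in replicates 2 and 3 at 72 h 0 did.

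A hypothesis is that these genes pass through a short pulse that the cultures reached at different times. If so, the 19 genes would also exceed all 66 h and 90 h libraries in other 72 h libraries. They did so for 12 of 19 genes in replicate 1 (63.2%), 5 in replicate 3 (26.3%) and 1 in replicate 2 (5.26%). Over all 7581 tested genes these 3 libraries did so for 6.93%, 4.23% and 10.4%. Over the 968 genes that exceeded all 66 h and 90 h libraries in replicate 4, a closer measure, they did so for 20.1%, 7.44% and 8.68%. Shifting the 19 genes together along the numbering, runs kept, gave at least as many in 1, 10 and 6223 of 7580 shifts. Replicate 2 thus showed no more than genes at other positions, and replicates 1 and 3 showed more. Genes reached by a shift were not chosen for being high in replicate 4, so the shifts do not allow for that choice. The order of the libraries was not tested, and a pulse in these cultures could also be a feature of single flasks. The time label of replicate 4 stays open too, so the 19 genes are not evidence on 72 h as such.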
